A study of Mus musculus with 6 samples.

How the data were processed

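Expression was measured in 6 mouse kidney samples, 1 Affymetrix array for each combination of 3 clamp times (0, 45 and 60 min) and 2 days (1 and 3). Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made with a 3' IVT kit. Such a kit copies RNA from its 3' end, so degraded RNA shows as a raised ratio of 3' to 5' control probe sets. The deposited values are intensities on a linear scale, 1 per probe set and array, and Affymetrix Expression Console is named as the tool per the submitters' processing notes. Its version and the algorithm used to summarise probes are not given in the sources used here. From the deposited intensities, the mean of each array after trimming the lowest and highest 2% was the same on all 6 arrays (500.003), so the values had been scaled to a common target. That scaling fixes each array's mean, and a change in many bright genes would shift the others.

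Of 45101 probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none in the platform annotation. Of those with 1 symbol, 34754 matched a gene identifier in the reference gene table, which changed 0 symbols. Probe sets with several symbols or none were not used for genes. Each of 18193 genes was represented by its probe set with the highest mean log2(intensity + 16). Genes were kept when that mean lay at or above the 40th percentile of all non-control probe sets (log2 6.01), which left 12735. Adding 16 damps noise in dim probe sets and makes fold changes of dim genes smaller than their ratios of intensity.

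Differences were tested with limma 3.58.1 in R 4.3.3 (eBayes, Benjamini-Hochberg adjusted p under 0.05). Clamped against 0 min (the mean of 45 and 60 min minus 0 min) and 60 against 45 min came from a fit of clamp time plus day. Day 3 against day 1 in clamped kidneys, and the change of the clamp effect between days, came from a fit of 4 cells (0 min or clamped, by day) in which the 45 and 60 min kidneys of a day share a cell. Each fit had 2 residual degrees of freedom. In the first fit an effect that differs between days counts as spread, and in the second the difference between 45 and 60 min does. The other 7 comparisons set 1 array against another and were called by size, at 2-fold, with no p-value. Correlations and overlaps between comparisons were given only where these share 0 arrays.

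Lists of genes for 30 pathways and cell types were fixed before the data were examined, as were the tests and most of the other settings tried. They held 582 symbols, of which 533 were on the array and 482 passed the filter, and some genes stand in more than 1 list. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 30 lists. The test was repeated with a correlation estimated from the arrays. In that form camera takes its degrees of freedom from the residual of the fit, 2 here, and not from the number of genes. It then has little power at any correlation, so its adjusted p does not measure correlation alone. The number of members past an adjusted p under 0.05 was also counted when adjusted over the list alone. For single-array comparisons, a list's median was placed among 10000 random lists of the same size and level.

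Genes were named by rule. For each limma contrast these were up to 8 genes per direction with an adjusted p under 0.05 and the same sign in every single-array difference. Where fewer passed, the places went to those with the largest smallest single-array difference. For each single-array comparison the 4 highest and 4 lowest genes were named, and in each list up to 4 members with the largest absolute fold change. Tnf, Tnfrsf1a, Tnfrsf1b, Havcr1, Lcn2, Slc34a1 and Umod were always named, and predicted or unnamed genes were passed over. Where 5 or fewer members of a list passed when adjusted over the list alone they were named too, chosen after their values were seen, as were the genes of the closing paragraphs on immunoglobulin genes.

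The fits were tested on simulated arrays with the real genes' means and residual spread and 200 changed genes. At an adjusted p under 0.05, changes of log2 size 1, 2 and 3 were recovered in 25.4%, 73.1% and 89.4% for clamped against 0 min, and in 28.4%, 77.6% and 93.9% for 60 against 45 min. For clamped kidneys of day 3 against day 1 the shares were 0%, 37.3% and 77.3%, and for the change of the clamp effect 0% at each size. In the simulation of clamped against 0 min, a shifted list had a camera adjusted p of 1.16e-31, and 0 of 20 other lists were called. The simulated genes varied independently and the lists were random. In the real data the estimated correlation was 0.86 for monocyte and macrophage markers in this contrast. The simulation therefore cannot tell how often lists of correlated genes are called falsely.

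Alternatives tried were quantile normalization, median centring, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, leaving out probe sets of the _x_at and _s_at kinds, and pseudocounts of 1 and 64. For limma they were also a robust variance trend, no moderation, a threshold of 0.1, clamping as a factor of 2 levels, the 4 clamped arrays alone, and leaving out each array. Single-array counts were repeated at 1.5-fold and 3-fold and with other 0 min arrays, and camera with ranks. Camera with each array left out, and list-alone counts under every limma alternative, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

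Among the lists not called for clamped against 0 min, the camera adjusted p was 0.250 for podocyte markers and 0.436 for red blood cell markers (1 gene). It was 0.629 for the sex-linked label check and 0.729 for adrenal cortex (2 genes). It was 0.861 for endothelium and for perirenal fat and 0.876 for heat shock proteins.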

Results

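RNA from mouse kidney was hybridised to 6 Affymetrix expression arrays, 1 for each combination of 3 clamp times and 2 collection days. The vessels of 1 kidney were clamped for 0, 45 or 60 min and released, which stops and then restores its blood flow (ischemia-reperfusion). Kidneys were taken at day 1 or day 3. The animals were male FVB/N mice of 6 to 8 weeks and 22 to 26 g. The series concerns blockade of TNF, an inflammatory cytokine, after this injury. Kidneys given such a treatment are not analysed here. Median intensities of the 6 arrays lay between 81.1 and 95.0, and between 18.4% and 20.6% of probe sets fell below an intensity of 16. Across genes, which are not independent replicates, log2 values correlated least between 0 min day 1 and 60 min day 3 (r = 0.931) and most between 45 min and 0 min at day 3 (r = 0.983). The log2 ratio of the 3' to the 5' beta-actin control probe set, a sign of RNA quality, was 1.03 to 1.12 on the day 1 arrays and on the 45 min day 3 array. It was 0.77 on the 0 min day 3 array and 0.49 on the 60 min day 3 array. The Gapdh ratio was -0.20 to -0.23 at day 1 and -0.33 to -0.37 at day 3.

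No combination of clamp time and day had a second array, and whether 1 array held RNA of 1 animal is not stated in the labels. The p-values therefore set each contrast against the residual spread of the 6 arrays around the fitted model, with 2 residual degrees of freedom, and the number of arrays limits the precision. Changes are log2 differences of intensity plus 16, which understate the change of dim genes, and are given ± SE from limma where a contrast was fitted. Of 12735 genes tested, limma called 0 in each of its 4 contrasts at an adjusted p under 0.05. The single genes named for these contrasts are thus described by size and did not pass the test over all genes. At an unadjusted p under 0.05, 1853 genes differed between clamped and 0 min kidneys and 1655 between 60 and 45 min. By the same measure 523 differed between clamped kidneys of day 3 and day 1, and 280 in the change of the clamp effect between days. Chance alone gives 636.75 in each.

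The first comparison asks what clamping did to kidney expression over both times and days. Markers of injured tubules were higher in clamped kidneys. Havcr1, which encodes the injury molecule KIM-1, went from an intensity of 599 at 0 min to 4216 at 45 min and 13011 at 60 min on day 1. It went from 1242 to 2548 and 11483 on day 3 (log2 difference 2.85 ± 0.37). Lcn2, which encodes the iron-binding lipocalin NGAL, was higher by 2.29 ± 0.19, the keratin gene Krt20 by 2.43 ± 0.18 and Sprr2f by 2.51 ± 0.32. Of the 22 measured tubular injury markers, 20 rose when adjusted over the list alone (0 over all genes tested), with a list median of 1.49. The list stood above other genes by camera (adjusted p = 1.83e-19). It had an adjusted p = 0.386 with an estimated correlation, a form of the test that rests on 2 degrees of freedom. Ranked by the smallest of the 4 differences from the 0 min kidney of the same day, the chemokine gene Ccl20 came first (3.23 ± 0.20, limma adjusted p = 0.135). Its intensities of 5.73 and 5.57 on the 0 min arrays lay below the added 16, which sets the size of its difference (4.81 with a pseudocount of 1 and 1.87 with 64). By that measure 23 genes were at least 2-fold higher in each clamped kidney and 0 lower. They included Ankrd1 (2.57 ± 0.39), Dscc1 (2.39 ± 0.22), Clec4d (2.00 ± 0.36), Il1f6 (1.98 ± 0.17), the amino acid transporter gene Slc7a12 (1.95 ± 0.34) and Hhat (1.54 ± 0.14). Dscc1 was also near background at 0 min (8.59 and 10.7), as was Hhat on the 0 min day 3 array (13.7). The genes lower in every clamped kidney by the largest margin were Prom2 (-1.41 ± 0.16), F2rl2 (-0.90 ± 0.16), the oxysterol hydroxylase gene Cyp7b1 (-2.58 ± 0.77), Slc22a26 (-1.44 ± 0.22) and the creatine kinase gene Ckb (-0.95 ± 0.15). They were followed by Sh3tc1 (-0.87 ± 0.17), Rdh16f2 (-0.98 ± 0.13) and the nuclear receptor gene Nr0b2 (-0.93 ± 0.14). Limma called 205 genes (178 higher, 27 lower) without the 45 min day 3 array, and 74 (65 higher, 9 lower) with a robust variance trend. Without variance moderation, 0 injury markers passed when adjusted over the list alone, and 11 passed with clamping as a factor of 2 levels.

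**Figure D1:**
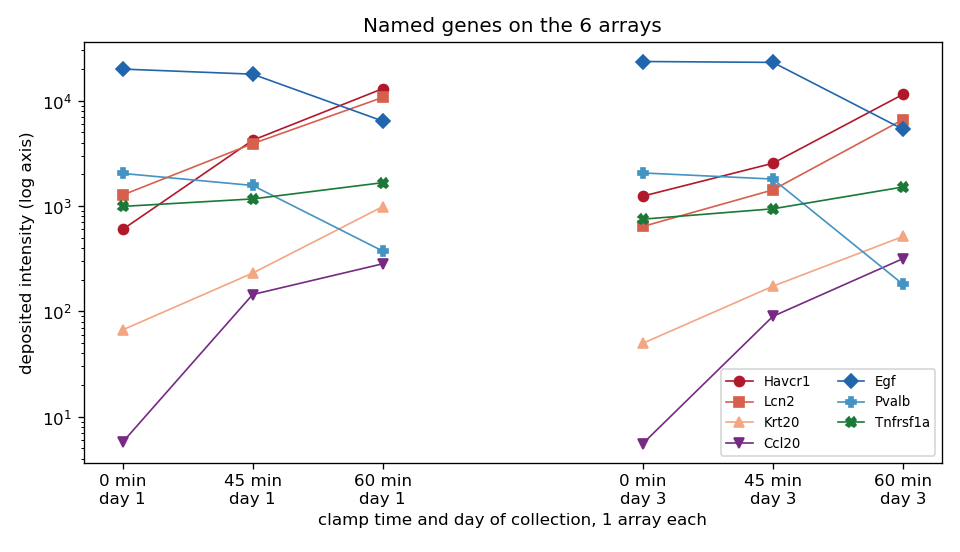
Deposited intensity (log axis) of 7 named genes on the 6 arrays, ordered by clamp time within each day, 1 point per array and no error bars because each combination had 1 array. Havcr1, Lcn2, Krt20, Ccl20 and Tnfrsf1a were highest at 60 min on both days, where Egf and Pvalb were lowest.

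Genes of the TNF pathway were the next group, given the subject of the series. Tnf itself was dim, with intensities of 9.49, 4.43 and 9.41 at 0, 45 and 60 min on day 1 and of 18.4, 36.3 and 73.4 on day 3. It lay below the intensity filter. Tnfrsf1a, which encodes TNF receptor 1, had intensities of 992, 1169 and 1667 on day 1 and 751, 942 and 1516 on day 3 (0.57 ± 0.13). Tnfrsf1b, for TNF receptor 2, was higher by 0.44 ± 0.14. Among 22 TNF signalling components, Tnfrsf1a, the adaptor gene Traf1 (1.16 ± 0.22) and the necroptosis genes Mlkl (0.96 ± 0.22) and Ripk3 (0.75 ± 0.14) rose when adjusted over the list alone. The list median was 0.19 (limma camera adjusted p = 0.00476; adjusted p = 0.395 with an estimated correlation). Of this list, 0 members passed without either 0 min array, the 45 min day 1 array or the 60 min day 3 array, 1 without the 60 min day 1 array, 0 without variance moderation and 1 with clamping as a factor of 2 levels. Among 30 TNF and NF-kB target genes, 19 rose when adjusted over the list alone, with a median of 0.85. They included Cxcl2 (2.37 ± 0.29) and the feedback inhibitor gene Socs3 (1.98 ± 0.17), while the neutrophil chemokine gene Cxcl1 was higher by 2.47 ± 0.54. Among 22 chemokines and leukocyte adhesion molecules, 18 rose when adjusted over the list alone, with a median of 1.25 (Ccl5, 1.64 ± 0.17). Among 17 immediate early genes, which respond first to stimuli and stress, 11 rose when adjusted over the list alone, with a median of 0.99, including Atf3 (1.54 ± 0.17) and Fos (1.40 ± 0.17). The camera adjusted p was 4.31e-14, 1.06e-12 and 5.05e-10 for these 3 lists, and each had an adjusted p = 0.386 with an estimated correlation. Without the 0 min day 3 array, 7 TNF and NF-kB targets, 8 chemokine genes and 6 immediate early genes passed when adjusted over the list alone. Without variance moderation 3, 1 and 0 did, and with clamping as a factor of 2 levels 0 immediate early genes and 11 TNF and NF-kB targets did.

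Cell cycle and matrix genes were also higher in clamped kidneys on average, least so in the 45 min day 3 kidney. There the cell cycle median was 0.13 over the 0 min kidney, with 0 of 30 genes at least 2-fold higher, and the matrix median 0.45 with 2 of 23. Among 30 cell cycle genes, 26 rose when adjusted over the list alone, with a median of 1.70 (camera adjusted p = 7.95e-14; adjusted p = 0.386 with an estimated correlation). The mitotic kinase gene Cdk1 was higher by 3.41 ± 0.77, from a base near background on the 0 min day 1 array (intensity 2.22), and the proliferation marker Mki67 by 2.57 ± 0.58. Among 23 genes of extracellular matrix and fibroblast activation, 22 rose when adjusted over the list alone, with a median of 1.04 (camera adjusted p = 2.82e-15; adjusted p = 0.386 with an estimated correlation). They included Postn (2.20 ± 0.39), the collagen genes Col3a1 (2.00 ± 0.38) and Col1a1 (1.99 ± 0.55), and Tnc (1.65 ± 0.14). Markers of resident fibroblasts and pericytes had a median of 0.68 over 9 genes, with 0 passing when adjusted over the list alone (camera adjusted p = 9.23e-04; adjusted p = 0.395 with an estimated correlation). The counts adjusted over the list alone depended on single arrays. For cell cycle genes the count was 0 without the 0 min day 1 array and 0 without the 60 min day 3 array, and for matrix genes it was 2 without the 0 min day 1 array. Without variance moderation 0 genes of either list passed, and with clamping as a factor of 2 levels 0 cell cycle genes did.

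Leukocyte markers moved unevenly. Of 22 monocyte and macrophage markers, Cd14, Lyz1 and Msr1 rose when adjusted over the list alone (Cd14 1.51 ± 0.19, Msr1 1.55 ± 0.29), with a list median of 1.11 (camera adjusted p = 1.77e-08; adjusted p = 0.395 with an estimated correlation). The neutrophil list (9 genes) had a median of 0.34, and Clec4d alone passed (camera adjusted p = 0.00294; adjusted p = 0.386 with an estimated correlation, and 0.104 without the 0 min day 3 array). In the lymphocyte list of 4 genes, Cd8a (-0.53 ± 0.16) and Ighm (-0.94 ± 0.24) fell when adjusted over the list alone, while the list itself was not called (camera adjusted p = 0.0706; adjusted p = 0.386 with an estimated correlation). Interferon-stimulated genes had a median of 0.47 over 21 genes, and Gbp2, Gbp3 and Iigp1 rose when adjusted over the list alone (camera adjusted p = 2.43e-06; adjusted p = 0.386 with an estimated correlation). Of 16 acute phase and complement genes, 6 rose when adjusted over the list alone, among them Fgb (1.66 ± 0.46), Saa3 (1.27 ± 0.27) and Osmr (1.10 ± 0.18), with a list median of 0.65 (camera adjusted p = 2.52e-05; adjusted p = 0.386 with an estimated correlation). Of 16 p53 target genes, Btg2, Eda2r and Gadd45a rose when adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.00476; adjusted p = 0.386 with an estimated correlation, and 0.204 without the 0 min day 3 array). The macrophage count was 0 without the 0 min day 3 array and 20 without the 60 min day 1 array. With 1 array left out, the acute phase count ran from 1 (without 0 min day 1) to 10 (without 45 min day 1). The interferon count ran from 0 (without either 0 min array, 45 min day 1 or 60 min day 3) to 8 (without 60 min day 1) and the p53 count from 0 (without either 0 min array or 60 min day 3) to 5 (without 45 min day 3). The neutrophil and lymphocyte counts were 0 without either 0 min array, and the neutrophil count was 3 and the lymphocyte count 1 without 60 min day 1. The lymphocyte count was also 0 without 60 min day 3. Without variance moderation, and with clamping as a factor of 2 levels, 0 genes of the macrophage, interferon and acute phase lists passed when adjusted over the list alone, and 1 and 0 p53 target genes did.

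Nephron segment and metabolic genes were lower in clamped kidneys on average, and all lists but NRF2 targets more so at 60 min on both days. Proximal tubule transporters had medians of -0.0055 and -0.08 at 45 min of day 1 and day 3, against -0.35 and -0.67 at 60 min. Genes of gluconeogenesis and amino acid metabolism had -0.13 and -0.11 at 45 min, against -0.69 and -0.62 at 60 min. Of 15 markers of the loop of Henle and distal nephron, 9 fell when adjusted over the list alone, with a median of -0.70. The calcium-binding protein genes Pvalb and Calb1 differed by -1.59 ± 0.28 and -1.23 ± 0.28, and the sodium-calcium exchanger gene Slc8a1 by -1.13 ± 0.21. Umod, the abundant loop of Henle transcript, differed by -0.17 ± 0.15 and turned to 0.05 after quantile normalization. Of 18 genes of gluconeogenesis and amino acid metabolism of the proximal tubule, 6 fell when adjusted over the list alone (Ddc -0.63 ± 0.13), with a median of -0.29, and the tyrosine catabolism gene Hpd was lower by -1.82 ± 0.55. The 35 proximal tubule transporters had a median of -0.28 with 0 passing when adjusted over the list alone. The organic anion transporter gene Slc22a7 differed by -1.41 ± 0.66 and the phosphate transporter gene Slc34a1 by -0.27 ± 0.12. Medians were -0.38 for 14 collecting duct markers, -0.29 for 25 genes of fatty acid oxidation and peroxisome, -0.21 for 26 genes of oxidative phosphorylation and -0.17 for 12 NRF2 target genes, each with 0 genes passing when adjusted over the list alone. The camera adjusted p was 1.41e-08 for the loop, 6.29e-07 for gluconeogenesis and for oxidative phosphorylation, 3.32e-06 for proximal transporters, 3.56e-06 for fatty acid oxidation, 5.91e-06 for the collecting duct and 0.0104 for NRF2 targets. With an estimated correlation the adjusted p = 0.395 for oxidative phosphorylation and NRF2 targets and 0.386 for the others, and the NRF2 target genes had 0.0986 after quantile normalization. Among random lists of like level, as a description of single arrays, oxidative phosphorylation lay at percentiles 68.7 and 16.7 at 45 and 60 min of day 1. At day 3 it lay at 2.40 and 1.71. Proximal transporters lay at 96.8, 0.02, 1.34 and 0 in the same order. The day 1 fall of oxidative phosphorylation was thus not set apart from genes of like level. At 60 min the loop, gluconeogenesis, fatty acid oxidation and collecting duct lists lay at 0.06 or below on both days. Without either 0 min array, 0 loop genes and 0 gluconeogenesis genes passed when adjusted over the list alone. The gluconeogenesis count was 1 without the 45 min array of either day and 0 without the 60 min array of either day, and the loop count was 6 without the 60 min day 1 array and 1 without variance moderation. With clamping as a factor of 2 levels, 0 loop and 0 gluconeogenesis genes passed when adjusted over the list alone.

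Lists of hypoxia and glycolysis genes, podocyte, red blood cell, adrenal cortex, endothelium and perirenal fat markers, heat shock proteins, genes of ER stress and the sex-linked label check were not called in clamped against 0 min kidneys (camera adjusted p from 0.0626 for hypoxia and glycolysis genes to 0.975 for ER stress and integrated stress response). After the filter the red blood cell list held 1 gene and the adrenal cortex list 2, so their results say little about these cell types. Ucp1 passed alone in the fat list when adjusted over the list alone, and 0 passed without the 0 min day 3 array. Median and mean differed in sign for heat shock proteins (-0.07 and 0.04, camera direction down), perirenal fat (-0.10 and 0.12, up), endothelium (-0.03 and 0.05, up) and ER stress genes (-0.02 and 0.04, up).

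**Figure D2:**
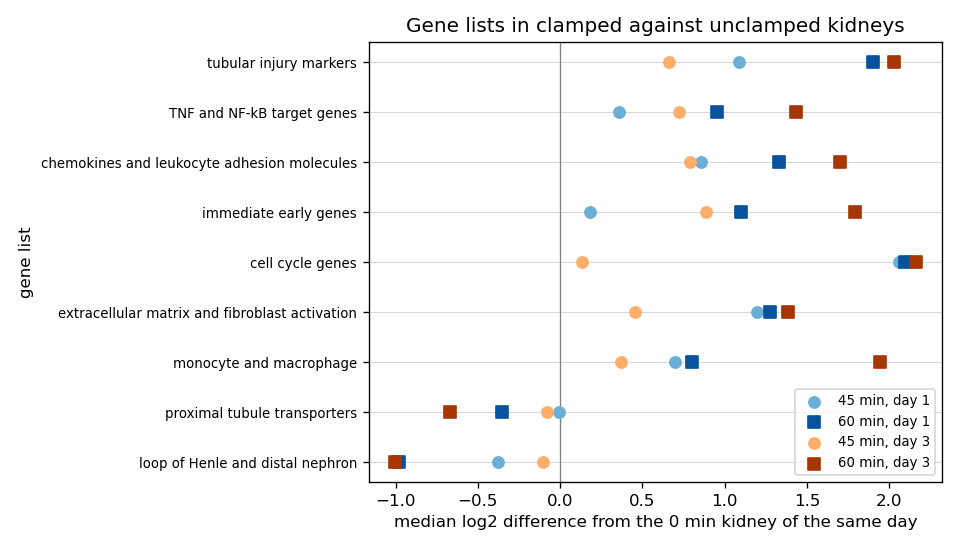
Median log2 difference from the 0 min kidney of the same day (x axis) for 9 gene lists (y axis) in each of the 4 clamped kidneys, 1 array each, so no error bars are drawn. The 60 min kidneys lie farthest from 0 in most lists, and the 45 min day 3 kidney lies at 0.13 for cell cycle genes against 2.06 to 2.16 in the other 3.

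The second comparison asks what the longer clamp added to the shorter one. Injury markers were higher after 60 than after 45 min. Sprr2f was higher by 3.75 ± 0.37, from intensities of 107 to 961 at day 1 and 81.7 to 2202 at day 3, Havcr1 by 1.89 ± 0.43, Lcn2 by 1.83 ± 0.22 and Krt20 by 1.75 ± 0.20. Rhbdf2, which encodes iRhom2, a partner of the protease that releases TNF from cells, was higher by 2.15 ± 0.33. Ccn1 (1.88 ± 0.34), Mab21l3 (1.77 ± 0.21), Fosl1 (1.70 ± 0.34) and Akr1b8 (1.59 ± 0.18) were among 42 genes at least 2-fold higher on both days, and Mab21l3 was below 16 at 45 min on day 3 (12.6). Among 33 genes at least 2-fold lower on both days were Pvalb (-2.62 ± 0.32), the distal tubule growth factor gene Egf (-1.79 ± 0.20) and Slc22a7 (-2.33 ± 0.77). Egf went from 17862 to 6409 at day 1 and from 23110 to 5356 at day 3. Also lower on both days were Tmem207 (-1.69 ± 0.23), C1qtnf3 (-1.58 ± 0.20), Myo5a (-1.46 ± 0.30), Rnf24 (-1.38 ± 0.53) and Prdm16os (-1.36 ± 0.17). Limma called 0 of these genes (smallest adjusted p = 0.307, with 1655 genes at an unadjusted p under 0.05), and 0 under every other setting tried.

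Of 22 tubular injury markers, 18 were higher at 60 min when adjusted over the list alone, with a median of 1.10. So were 14 of 30 TNF and NF-kB target genes (0.77), 10 of 17 immediate early genes (0.97), and 8 of 22 chemokines and leukocyte adhesion molecules (0.74), a list in which 1 gene was lower. Mlkl (1.39 ± 0.25), Ripk3 (1.11 ± 0.17) and Tnfrsf1b (0.78 ± 0.16) passed among the TNF signalling components (median 0.27), and Tnfrsf1a differed by 0.59 ± 0.15. Lower at 60 min were 8 of 15 loop of Henle and distal nephron markers (median -0.76, Calb1 -1.92 ± 0.32) and 8 of 18 gluconeogenesis and amino acid genes (-0.52, Aadat -1.40 ± 0.20, G6pc -1.12 ± 0.19), adjusted over the list alone. So were 2 of 35 proximal tubule transporters (-0.48, Slc22a30 and Slc7a13) and 1 of 14 collecting duct markers (-0.40, Atp6v1b1), each adjusted over the list alone. The camera adjusted p was 2.03e-14 for injury, 2.79e-09 for TNF and NF-kB targets, 2.82e-08 for immediate early genes, 1.29e-05 for chemokines and 1.28e-04 for TNF components. With an estimated correlation the adjusted p = 0.482 for injury and 0.501 for the other 4. The camera adjusted p was 4.76e-10, 4.76e-10, 8.16e-12 and 2.06e-06 for the 4 lower lists in the order given. With an estimated correlation the adjusted p = 0.501 for the collecting duct and 0.482 for the other 3. Slc34a1 differed by -0.49 ± 0.14 and Umod by -0.32 ± 0.17. The counts of higher genes rested on the 60 min day 3 array. Without it 7 injury markers and 0 genes of the TNF target, chemokine, immediate early and TNF component lists passed when adjusted over the list alone. The TNF target count was 2 without 45 min day 1 and 8 without 45 min day 3, the chemokine count 12 without 60 min day 1, and the TNF component count 2 without either 0 min array, 4 without 45 min day 1 and 0 without 60 min day 1 or 45 min day 3. The loop count was 4 without 60 min day 3. Gluconeogenesis counts were 3 without 45 min day 1, 1 without either 0 min array or 60 min day 1, and 0 without either other array. The transporter count was 5 without 60 min day 1 and 0 without any other array. The collecting duct count was 2 without either day 1 clamped array and 0 without any other array. Without variance moderation 0 injury, immediate early, TNF component and loop genes passed when adjusted over the list alone, and 1 TNF target, 1 chemokine gene and 4 gluconeogenesis genes did.

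Other lists shifted at 60 against 45 min with few or no single genes passing when adjusted over the list alone. Cell cycle genes had a median of 1.12 with 0 passing (camera adjusted p = 2.79e-07; adjusted p = 0.501 with an estimated correlation). Matrix genes had 0.53 with Tagln (1.39 ± 0.24) and Tnc (1.13 ± 0.16) passing (7.01e-06; adjusted p = 0.501 with an estimated correlation), and monocyte and macrophage markers 0.84 with Cd14 passing (2.49e-05; adjusted p = 0.556 with an estimated correlation). These 3 lists differed by day. Their single-array medians at day 1 and day 3 were 0.10 and 2.02 for cell cycle genes, 0.11 and 1.01 for matrix genes and -0.03 and 1.60 for macrophage markers. Oxidative phosphorylation had a median of -0.30 (4.74e-09; adjusted p = 0.501 with an estimated correlation) and fatty acid oxidation of -0.26 (5.26e-07; adjusted p = 0.482 with an estimated correlation). The camera adjusted p was 0.00748 for interferon-stimulated genes (median 0.40), 0.00769 for perirenal fat (-0.39), 0.00842 for acute phase and complement genes (0.39, with Fgg, Lrg1, Saa2 and Serpina3n passing) and 0.0201 for p53 target genes (0.37, with Btg2 and Eda2r passing). With an estimated correlation these had an adjusted p = 0.556, 0.501, 0.482 and 0.501. NRF2 target genes were not called, and their median of -0.13 and mean of 0.02 differed in sign. The shifts of cell cycle genes, of the extracellular matrix and fibroblast activation list and of monocyte and macrophage markers were not called without the 45 min day 3 array (limma camera adjusted p = 0.0608, 0.0843 and 0.0843). That of the macrophage list was not called without the 60 min day 3 array either (0.898). Without the 45 min day 1 array, 27 cell cycle, 15 matrix and 10 macrophage genes passed when adjusted over the list alone, and the calls of p53 target genes (0.451) and of acute phase and complement genes (0.0645) were lost. Without 60 min day 1, 19 macrophage genes passed and the fat call was lost (0.0765). Interferon-stimulated genes were not called without 45 min day 3 (0.0843) or 60 min day 3 (0.512), nor perirenal fat without 45 min day 3 (0.0843). The acute phase count was 1 without 45 min day 3 and 0 without any other array, and the p53 count 2 without 60 min day 1 and 0 without any other. Without variance moderation 1 acute phase gene and 0 matrix, macrophage and p53 genes passed.

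The third comparison asks how clamped kidneys differed between day 3 and day 1. The class II antigen presentation genes H2-Aa (2.13 ± 0.17, adjusted p = 0.457) and Cd74 (2.04 ± 0.19, adjusted p = 0.563) were higher at day 3 by limma's estimate. H2-Aa had intensities of 793 and 768 at day 1 and 3555 and 3372 at day 3 against 2024 and 2252 in the 0 min kidneys. Ccl8 (1.97 ± 0.30), Ubd (2.04 ± 0.68), Nr4a3 (1.71 ± 0.25), the adhesion molecule gene Vcam1 (1.53 ± 0.58), the clock gene Npas2 (1.48 ± 0.56) and Ms4a4c (1.41 ± 0.28) were also higher. The fatty acid hydroxylase gene Cyp4a14 differed by -4.52 ± 0.29 (limma adjusted p = 0.294), from 13595 and 8576 to 407 and 506. It was lower in the 0 min kidneys too, from 16833 to 1603. Also lower were the fibrinogen genes Fgb (-2.51 ± 0.44) and Fgg (-1.79 ± 0.40), the clock output gene Dbp (-2.10 ± 0.76), Serpina6 (-1.98 ± 0.47), Fabp1 (-1.94 ± 0.27), Reep6 (-1.45 ± 0.18) and the export pump gene Abcc2 (-1.32 ± 0.35). Fabp1 lay below 16 on the 45 min day 3 array (13.0). Between the 0 min kidneys Ccl8 differed by 1.81 and Abcc2 by -1.05, so their changes were not particular to clamped kidneys. Cd74 differed there by 0.46. Havcr1 differed by -0.45 ± 0.88, Lcn2 by -1.07 ± 0.86, Tnfrsf1a by -0.22 ± 0.32, Tnfrsf1b by 0.21 ± 0.40 and Umod by 0.11 ± 0.24. Each of these turned in sign when 1 array was left out (without the 45 min day 3 array, Havcr1 0.63, Lcn2 0.03, Tnfrsf1a 0.12 and Umod -0.15; without the 60 min day 3 array, Tnfrsf1b -0.26). Slc34a1 differed by 0.43 ± 0.28. Limma called 0 genes here (523 at an unadjusted p under 0.05) and 0 in every other setting tried.

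Among the lists, limma's camera gave monocyte and macrophage markers the lowest adjusted p between the days (median 1.05, adjusted p = 1.34e-09; adjusted p = 0.851 with an estimated correlation), with Lyz2 higher by 2.05 ± 0.56 and Ms4a7 by 1.72 ± 0.58. TNF and NF-kB target genes (median 0.43, 1.61e-06), genes of ER stress (0.44, 3.26e-05), immediate early genes (0.54, 6.91e-05), heat shock proteins (0.48, 6.91e-05), chemokines (0.55, 1.57e-04) and neutrophil markers (0.51, 3.79e-04) were also higher as lists, each with an adjusted p = 0.851 with an estimated correlation. So were perirenal fat (0.37, 0.00288), interferon-stimulated genes (0.18, 0.00433), lymphocyte markers (0.42, 0.0118), matrix genes (0.26, 0.0224) and resident fibroblasts (0.32, 0.0416), with an adjusted p = 0.869 with an estimated correlation for matrix genes and 0.851 for the other 4. Fatty acid oxidation (-0.24, 6.91e-05) and collecting duct (-0.39, 0.00861) were lower, each with an adjusted p = 0.851 with an estimated correlation. Between the 0 min kidneys, medians of day 3 minus day 1 were -0.20 for fatty acid oxidation, -0.32 for collecting duct and 0.49 for lymphocyte markers. They were 0.63 for macrophage markers and 0.44 for matrix genes. These lists thus moved the same way without clamping. Medians of the other called lists lay there between -0.08 and 0.21. Adjusted over the list alone, Ccl8, Cd8a and Cidea rose, and Cyp4a14, Fga, Fgb, Fgg and Nqo1 fell, the last 4 from lists that were not called. Of the 3 fibrinogen genes, 0 passed without 60 min day 3 and 1 without 60 min day 1 or 45 min day 3, and Ccl8 and Cd8a did not pass without 45 min day 1. Without 60 min day 1, Cd8a and Cidea did not pass, and Nqo1 did not pass without either of these arrays. Without 45 min day 3, 8 chemokine genes and 3 NRF2 target genes passed. Without variance moderation 1 lymphocyte gene and 0 genes of the other lists named here passed. Tubular injury markers were not called (median -0.02, mean -0.08, camera direction up), nor were proximal tubule transporters (median -0.02, camera direction up). Without the 60 min day 3 array, the array with the lowest actin 3' to 5' ratio, the calls of TNF and NF-kB target genes (0.306), of chemokines and leukocyte adhesion molecules (0.632), of immediate early genes (0.119), and of interferon-stimulated genes (0.927) were lost. So were those of fatty acid oxidation and peroxisome (0.861), of lymphocyte markers (0.0515) and of resident fibroblast and pericyte markers (0.580). The extracellular matrix and fibroblast activation list (0.0387) and the collecting duct list (0.580) turned in direction without that array. Without the 45 min day 3 array, heat shock proteins (0.0832), ER stress and integrated stress response (0.363), lymphocyte (0.0576) and perirenal fat (0.296) were not called, while 19 monocyte and macrophage markers and 20 cell cycle genes rose when adjusted over the list alone. Without the 45 min day 1 array, the calls of immediate early genes (0.215), matrix genes (0.175) and the collecting duct (0.183) were lost. Without the 60 min day 1 array, those of lymphocyte (0.0645), fibroblast (0.269) and perirenal fat (0.0645) markers were lost.

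The fourth comparison asks whether the effect of clamping changed from day 1 to day 3. Genes were ranked by the smaller of their changes at 45 and at 60 min, not by the fitted change. Both changes share the 0 min array of each day, so a shift of such an array alone moves both. The first 8 of those shifted towards higher values at day 3 included Batf3 (3.14 ± 0.72), Fcnb (2.98 ± 0.87), Oit1 (2.92 ± 0.33) and Tgfb3 (2.73 ± 0.61). The others were the TNF receptor family gene Relt (2.67 ± 0.34), Cxcl17 (2.37 ± 0.41), Ccnb1ip1 (2.19 ± 0.45) and Rasd2 (2.03 ± 0.30). By the fitted change, other genes stood above some of these. Among them, Igkv8-30 (3.63) stood above all 8 and Inhbb (2.60) above Cxcl17, Ccnb1ip1 and Rasd2. Azgp1 (2.36) and Apoh (2.24) stood above Ccnb1ip1 and Rasd2. All 8 ranked genes were dim on the 0 min day 3 array, with intensities from 2.43 for Tgfb3 to 28.3 for Rasd2. By the same ranking, the first 8 shifted towards lower values were the steroid reductase gene Akr1c18 (-3.59 ± 0.89), Wipf3 (-3.38 ± 0.81), the replication genes Pole (-3.14 ± 1.29) and Cdc45 (-2.66 ± 0.64), Pik3c2g (-3.06 ± 0.66), Alas2 (-2.43 ± 1.05), Lhpp (-2.39 ± 0.70) and Ptprcap (-2.07 ± 0.50). Among other genes, Cdk1 had a larger fitted change (-2.89) than Cdc45, Alas2, Lhpp and Ptprcap, and Birc5 (-2.18) than Ptprcap. Of the 8 genes, 5 were dim on the 0 min day 1 array, with intensities of 5.25 for Pole, 10.0 for Cdc45, 10.9 for Ptprcap, 11.1 for Lhpp and 22.1 for Wipf3. Limma's adjusted p was 1.00 for each, 0 genes were called, and 280 genes had an unadjusted p under 0.05. As lists by limma's camera, ER stress genes (median 0.56, adjusted p = 6.02e-04), TNF and NF-kB targets (0.51, 0.00137), heat shock proteins (0.49, 0.00399), hypoxia and glycolysis genes (0.21, 0.00754) and immediate early genes (0.42, 0.0116) shifted up, each with an adjusted p = 1.00 with an estimated correlation. Cell cycle genes (-0.85, 6.43e-04), podocyte markers (-0.47, 0.0212) and proximal tubule transporters (-0.29, 0.0281) shifted down, each also with an adjusted p = 1.00 with an estimated correlation. In all, 0 genes of any list passed when adjusted over the list alone. Without the 45 min day 3 array, 16 lists were called and the calls of ER stress and integrated stress response (0.118), heat shock proteins (0.155), hypoxia and glycolysis genes (0.118) and cell cycle genes (0.526) were lost. Without the 60 min day 3 array those of TNF and NF-kB target genes (0.450), immediate early genes (0.294), podocyte (0.0628) and proximal tubule transporters (0.428, in the other direction) were lost, and without the 45 min day 1 array those of the same 4 lists (0.0733, 0.352, 0.0733 and 0.429).

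The remaining comparisons set 1 array against another, have no replicate check and are given by size alone. At day 1, 453 genes were at least 2-fold higher and 135 lower at 45 min than at 0 min. Cdk1 (4.68), Akr1c18 (3.82), Fignl1 (3.61) and the mitotic gene Birc5 (3.54) were highest, and the immunoglobulin genes Igha (-5.13), Igkv8-30 (-4.85) and Jchain (-4.78) and the adipokine gene Azgp1 (-4.59) lowest. At 60 min on day 1, 555 genes were higher and 216 lower, led by Cdk1 (5.03), Havcr1 (4.40), Pole (4.22) and Uhrf1 (4.08), with Igkv9-120 (-2.95), Jchain (-2.79), Apoh (-2.75) and Igkv8-30 (-2.70) lowest. On the 0 min day 1 array Cdk1 (intensity 2.22), Pole (5.25), Fignl1 (6.81) and Birc5 (15.8) lay below the added 16, which limits the size of such differences and their order. Median differences at 45 and 60 min were 1.08 and 1.90 for tubular injury markers, 2.06 and 2.10 for cell cycle genes, 1.19 and 1.28 for matrix genes, 0.36 and 0.95 for TNF and NF-kB targets and -0.38 and -0.98 for the loop of Henle and distal nephron. Between 60 and 45 min on day 1, 128 genes were at least 2-fold higher and 125 lower, with Azgp1 (4.54), Sprr2f (2.99), Igha (2.65) and Cxcl1 (2.25) highest and Chil1 (-2.31), Sncb (-2.16), Tnfaip8l2 (-2.10) and Pvalb (-2.02) lowest. At 60 min Chil1 (8.80), Tnfaip8l2 (12.3) and Sncb (18.2) were near background, as was Azgp1 at 45 min (18.0).

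At day 3, 185 genes were at least 2-fold higher and 100 lower at 45 min than at 0 min (154 and 130 after quantile normalization, 131 and 141 after median centring). Cxcl1 (3.13), the insulin-like growth factor binding protein gene Igfbp1 (2.80), Inhbb (2.77) and Oit1 (2.68) were highest, and Zfp712 (-2.77), Fbxw16 (-2.48), Ly6i (-2.36) and Fbxo42 (-2.34) lowest. Zfp712 (6.17), Fbxw16 (6.47) and Ly6i (7.34) lay below the added 16 at 45 min, as did Oit1 at 0 min (7.38), so their differences have no firm order. At 60 min, 958 genes were higher and 295 lower than at 0 min (729 and 508 after median centring), led by Sprr2f (4.89), Ankrd1 (4.37), Ccl20 (3.95) and Cxcl2 (3.67), with Slc22a7 (-4.26), Cyp7b1 (-3.81), Pvalb (-3.40) and Slc22a19 (-3.23) lowest, and Ccl20 was below 16 at 0 min (5.57). Median differences at 45 and 60 min were 0.66 and 2.03 for tubular injury markers, 0.13 and 2.16 for cell cycle genes, 0.45 and 1.39 for matrix genes, 0.72 and 1.43 for TNF and NF-kB targets, 0.37 and 1.95 for monocyte and macrophage markers and -0.10 and -1.01 for the loop of Henle and distal nephron. Between 60 and 45 min on day 3, 758 genes were higher and 303 lower, with Sprr2f (4.51), the heme oxygenase gene Hmox1 (3.26), Cenpi (3.05) and Bub1 (3.01) highest and Igfbp1 (-3.35), Slc22a7 (-3.25), Pvalb (-3.21) and Zbtb16 (-3.14) lowest, and Cenpi was below 16 at 45 min (14.7). Median centring moved the median of all genes by -0.17 for 60 against 0 min at day 3 and by 0.12 for the 0 min kidneys of day 3 against day 1.

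The 2 kidneys with 0 min of clamping differed from each other by at least 2-fold in 393 genes, 218 higher and 175 lower at day 3 (302 and 125 after median centring), more than the 285 genes of 45 against 0 min at day 3. Akr1c18 (4.26), Pik3c2g (3.51), Cdk1 (3.09) and Birc5 (2.78) were higher at day 3, and Azgp1 (-4.84), Cyp4a14 (-3.38), the acute phase gene Saa1 (-2.80) and Npy (-2.71) lower. Cdk1 (2.22) and Birc5 (15.8) lay below 16 at day 1 and Azgp1 (12.5) at day 3. The list medians between these 2 kidneys were 1.21 for cell cycle genes, 0.63 for monocyte and macrophage markers, 0.44 for matrix genes and -0.20 for tubular injury markers. Comparisons without a shared array could be set side by side. The 60 against 0 min differences of day 1 and day 3 correlated across genes at r = 0.66, with 383 genes at least 2-fold higher on both days where independent lists would share 41.8, and 91 lower on both where 5.00 would be shared. For 45 against 0 min the correlation was r = 0.06, with 36 genes higher on both days against 6.58. For 60 against 45 min it was r = 0.31, with 42 genes higher and 33 lower on both days against 7.62 and 2.97.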

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

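The tests of the cell cycle and macrophage patterns in this part were chosen after the results were seen, while the tests of the change of the clamp effect between days were planned. For 8 gene lists the effect of clamping differed between day 1 and day 3 by camera, each with an adjusted p = 1.00 with an estimated correlation. The adjusted p was 6.02e-04 for ER stress, 0.00137 for TNF and NF-kB targets, 0.00399 for heat shock proteins, 0.00754 for hypoxia and glycolysis genes and 0.0116 for immediate early genes, all shifted up. It was 6.43e-04 for cell cycle genes, 0.0212 for podocyte markers and 0.0281 for proximal tubule transporters, all shifted down. Without 1 of the day 3 arrays or the 45 min day 1 array each call was lost. Cell cycle medians over 0 min were 2.06 at day 1 and 0.13 at day 3 at 45 min. At 60 min they were 2.10 and 2.16. ER stress medians were -0.43 and 0.60 at 45 min, and -0.18 and -0.09 at 60 min. Those of heat shock proteins were -0.45 and 0.34, and -0.30 and -0.17. For hypoxia genes they were -0.20 and 0.08, and -0.21 and -0.09. The change in these lists was thus larger at 45 min, with 1 array per day.

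Among 239 named genes, 31 moved one way in both clamped kidneys of day 1 and the opposite way in both of day 3. These differences were called by sign and were not tested gene by gene beyond limma's contrast, which gave an adjusted p = 1.00 for each and called 0 of 12735 genes (280 at an unadjusted p under 0.05). Of the 31, 13 had been named for their change between days. Of all genes tested, 1802 (14.15%) had such opposite directions. The 2 differences of a day share its 0 min array, so a shift of that array alone can give this pattern. From day 1 to day 3, Akr1c18 differed by 4.26 at 0 min, 0.11 at 45 min and 1.23 at 60 min. Cd74 differed by 0.46, 1.94 and 2.14 in the same order. The change from day 1 to day 3 was towards higher values for Batf3 (3.14), Fcnb (2.98), Oit1 (2.92), Tgfb3 (2.73), Relt (2.67), Cxcl17 (2.37), Ccnb1ip1 (2.19) and Rasd2 (2.03). Next came H2-Aa (1.97), Cd74 (1.58), Pdk4 (1.35), Cd83 (1.22), Tnf (1.15), Sesn2 (1.07) and Nr4a3 (1.03). Smaller changes in that direction were those of Hsp90b1 (0.95), Sdf2l1 (0.94), Ass1 (0.90), Ddit3 (0.67), P4ha1 (0.64) and Cidea (0.57). Tnf lay below the intensity filter, with 9.49, 4.43 and 9.41 at 0, 45 and 60 min of day 1, so its sign on that day was read from values near background. In 9 of the 31 genes the smallest of the 4 differences was under 0.1 in size. The change was towards lower values for Akr1c18 (-3.59), Wipf3 (-3.38), Pik3c2g (-3.06), Alas2 (-2.43), Lhpp (-2.39), Fabp1 (-1.49), Slc6a19 (-0.95), Clic5 (-0.74), Podxl (-0.68) and Trem3 (-0.23).

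Outside the genes, 4081 probe sets without a single gene symbol passed the intensity filter. Of these, 2 were at least 2-fold higher than the 0 min array of the same day on all 4 clamped arrays and 1 was lower.

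Cell cycle genes differed little between the 45 and 0 min kidneys of day 3, with a median of 0.13. The 0 min kidney of day 3 stood above that of day 1 by a median of 1.21, and the 45 min kidney of day 3 by 1.34, which restates these values and tests no explanation. Whether a high level in the 0 min kidney of day 3 was the whole of the pattern could not be decided from the 45 min kidneys. Their day 3 minus day 1 median was -0.58, from 1 array each, where the 0 min arrays differed by 1.21. The 60 min arrays differed by 1.19, so the 0 and 60 min kidneys moved alike and the 45 min kidneys the other way. Scaling of the arrays was examined only for the difference between the 0 min kidneys, which was 1.37 after quantile normalization. That normalization moved the median of all genes by 0.014 there and by -0.0052 for 45 against 0 min at day 3. An exchange of the 45 and 0 min arrays of day 3 was argued against by injury markers, higher at 45 min by 0.66. Why the 0 min kidneys differed, and whether a 0 min or a 45 min array stands apart, stays open. Each combination has 1 array, and the label does not say what was done at 0 min beyond the clamp time.

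Monocyte and macrophage markers were highest in the 60 min day 3 kidney, at a median of 1.95 over the 0 min kidney. A lower share of tubule cells, with all other cells unchanged, would raise other cell types alike. The endothelium median was 0.0136 there (-0.11 after quantile normalization and -0.16 after median centring). Medians were 0.16 for podocyte, 0.53 for neutrophil and 1.11 for resident fibroblast and pericyte markers. Whether clamping changed the numbers of these cells was not measured, so the medians cannot decide on a change in cell shares. The actin ratio of that array, 0.49, was the lowest of the 6, whereas degraded RNA raises it, and its Gapdh ratio and that of the 0 min array of day 3 were both -0.37. At 60 min on day 1 the markers were higher by 0.80 than in the 0 min kidney of that day, but differed by -0.0093 from that of day 3, while the 45 min kidneys were higher by 0.70 at day 1 and 0.37 at day 3, and other effects of array quality on the direction stay open. The excess over 60 min at day 1, a median of 1.74, cannot be told apart from an effect of that array's quality, because it rests on 1 array, and a larger number of macrophages at day 3 may be a biological explanation that stays untested.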

How the results depend on the processing

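Camera with 1 array left out, and list-alone counts under other settings, were chosen after the results were seen, and the other alternatives were planned. No paired analysis was possible because the labels give no replicate numbers, while day was a term of the fit of clamp times. Limma called 0 genes in all 4 contrasts under most settings, including a threshold of 0.1. For clamped against 0 min it called 1 gene after median centring, 74 with a robust variance trend, and 0 to 205 with 1 array left out. The cause was not tested.

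Gene values that turned in sign were mostly small against their error. After quantile normalization Umod was 0.046 for clamped against 0 min and -0.063 for day 3 against day 1, and after median centring the change of the clamp effect was -0.039 for Slc34a1. With 1 array left out, day 3 against day 1 ranged from -0.56 to 0.12 for Tnfrsf1a, -0.26 to 0.68 for Tnfrsf1b, -1.53 to 0.63 for Havcr1, -2.18 to 0.030 for Lcn2 and -0.15 to 0.37 for Umod. The change of the clamp effect ranged from -0.17 to 0.51 for Tnfrsf1a, -0.33 to 0.61 for Tnfrsf1b, -1.20 to 1.00 for Lcn2, -0.22 to 0.31 for Slc34a1 and -0.13 to 0.40 for Umod. These fits rest on fewer arrays. Of the values of single genes under all settings, 1751 kept direction and side of the threshold, 20 turned in sign, 19 passed a threshold they had missed and 1 moved. All 20 belonged to genes that were always named. Genes named for a contrast had been chosen for the same sign in all its single-array differences. Limma had also called 0 genes at the main settings, so the 1751 say little about stability.

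With an estimated correlation 0 lists were called in each contrast, against 20, 18, 14 and 8 with the preset one. The estimated form rests on 2 residual degrees of freedom, so the loss of calls does not by itself show correlation between genes. For clamped against 0 min the estimate was -0.058 for acute phase and complement genes and 0.0027 for neutrophil markers, below the preset one. Their unadjusted camera p still rose, from 1.26e-05 to 0.0427 and from 0.00166 to 0.0838. This argues against a higher correlation as the cause for these lists. The 2 degrees of freedom of that form raise p at any correlation. In the other lists called there the estimate was higher than the preset one, so both could raise p. The share of each was not tested. With 1 array left out 20 to 23, 15 to 21, 12 to 19 and 6 to 16 lists were called. Among the list calls, 60 were lost with an estimated correlation, 5 without the filter, 2 with the mean of probe sets, 2 after quantile normalization and 1 with ranks. Without 1 array, 13 were lost without 45 min day 3, 12 without 60 min day 3, 9 without 45 min day 1, 4 without 60 min day 1 and 2 without 0 min day 3. The direction turned for 3 lists when 60 min day 3 was left out. Over the arrays left out, the adjusted p ranged from 2.67e-09 to 0.175 for extracellular matrix and fibroblast activation and from 4.93e-07 to 0.580 for collecting duct, both day 3 against day 1, and from 4.80e-08 to 0.429 for proximal tubule transporters in the change of the clamp effect.

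Counts of single-array comparisons at 2-fold moved with the filter, and the cause was not tested. Without it they were 1432, 1652, 1123 and 2093 for 45 and 60 min of day 1 and 45 and 60 min of day 3, each against 0 min, 930 and 1908 for 60 against 45 min at day 1 and 3, and 1283 between the 0 min kidneys. With the filter at the 60th percentile they were 318, 461, 119, 793, 132, 657 and 178 in that order. A pseudocount of 64, which shrinks the changes of dim genes, gave 327, 485 and 104 for the first 3, 119 for 60 against 45 min at day 1 and 180 between the 0 min kidneys. At 1.5-fold the counts were 1807, 2295, 1238, 3020, 1222, 2979 and 1453, and at 3-fold 167, 263, 57, 446, 33, 301 and 110. Against the mean of both 0 min arrays 45 min at day 1 had 364, and against the 0 min array of day 1 45 min at day 3 had 453. Precision for dim genes is limited by signal near background, where 18.4% to 20.6% of probe sets lay under 16.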

Other observations

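The test of clock genes in this part was chosen after Dbp and Npas2 had been seen, with its prediction set before its result was seen, and the genes of the next 2 paragraphs were chosen after their values were seen. Immunoglobulin genes, made by plasma cells, varied between single arrays. Igha had intensities of 13435, 369 and 2395 at 0, 45 and 60 min on day 1 and of 10885, 12185 and 1587 on day 3. Jchain, which links secreted antibodies, followed with 4182, 137 and 592 and then 2534, 2989 and 379, and Igkv8-30 with 2936, 86.2 and 437 and then 918, 2472 and 269. The 45 min day 3 kidney lay near the 0 min kidneys in these genes and the other 3 clamped kidneys below them. Azgp1, an adipokine gene, stood at 802 and 773 in the 0 and 60 min kidneys of day 1 and between 11.6 and 18.0 in the other 4.

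Several heat shock and ER stress genes were higher in the 45 min day 3 kidney than in the 0 min kidney of that day. The differences at 45 and 60 min of day 1 and 45 and 60 min of day 3 were -0.60, -0.49, 2.46 and -0.41 for Hspa1a, which encodes the inducible chaperone HSP70. They were -1.21, -0.82, 1.10 and -0.64 for Hsph1, -0.39, -0.36, 1.00 and -0.78 for Herpud1, and -0.87, -0.45, 1.14 and -0.27 for Creld2. The medians of the heat shock proteins were -0.45, -0.30, 0.34 and -0.17, and those of ER stress genes -0.43, -0.18, 0.60 and -0.09, the last turning to 0.05 after quantile normalization. Among random lists of like level, as a description of single arrays, the heat shock medians lay in the same order at percentiles 0, 2.16, 100 and 37.9. Those of ER stress genes lay at 0, 6.39, 100 and 41.0. Hsp90b1, Sdf2l1 and Ddit3 were higher by 0.87, 0.63 and 0.35 in the 45 min day 3 kidney. In the 60 min day 3 kidney they were higher by 0.45, 0.45 and 0.30. Of the macrophage genes, Cd68 stood at 1.77, 2.07, -0.09 and 2.41 and Ms4a7 at 0.30, 0.39, 1.02 and 2.74. The difference between these 2 genes was not tested. Genes of oxidative phosphorylation had medians of -0.10, -0.28, -0.05 and -0.47, the first turning to 0.04 after quantile normalization.

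The lower Dbp and higher Npas2 at day 3 may reflect another phase of the circadian clock at collection. A fixed set of 9 other clock genes, each signed by its phase relative to Npas2, was to shift by at least 0.5 at each clamp time if so and by under 0.2 at 1 or more if not. The signed median was 0.26 at 0 min, 0.43 at 45 min and 1.09 at 60 min, so the lowest value lay between the bounds and left the explanation open. At 0 min 7 of the 9 genes moved in the predicted direction, and at 45 and 60 min 9 of 9 did. The medians lay at the 98.6th, 99.8th and 100th percentile of random lists of the same size and level, as a description of single arrays, and the labels used here give no hour of collection.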
